A study of Drosophila melanogaster with 8 samples.

How the data were processed

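The values come from RNA that was extracted with Trizol from eRpL22 or eRpL22-like immunoprecipitates of testis lysates of wild-type flies, per the labels' protocols. Libraries were made with the Kapa Hyper prep kit and sequenced as single reads on an Illumina HiSeq instrument, per the same protocols. The submitters' processing notes name Trim Galore, cutadapt, STAR and DESeq2 without versions. The genome build, the gene annotation and the read counter are not given in the sources used here, nor is whether counting used strand, so no coordinates are printed.

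The deposited table lists 12051 genes, 10686 of them marked protein-coding. For each gene it gives the authors' log2 fold change of eRpL22-like over eRpL22, their Wald statistic (a score), their p-value and their adjusted p-value, per the file headers. It also gives the authors' normalized expression for 7 libraries, a signal that is never negative. Column names were read as eRpL22 or eRpL22-like and a replicate number from their match to the sample titles. No column matched eRpL22 replicate 4, which was not analysed here, and 0 other columns of per-sample values were left unused. Each deposited signal value was a whole number of reads divided by a factor of its library: 100% of the values came out whole at a relative tolerance of 1e-06. Median-of-ratios factors recomputed from those reads matched the deposited ones to within 2.44e-15. The authors' adjusted p-values equalled a Benjamini-Hochberg adjustment of their p-values over the 12051 genes to within 4.25e-14. A DESeq2 fit of the recovered reads gave the authors' log2 fold change to within 0.01 for 11110 of the 12051 genes (92.2%).

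Totals of recovered reads, from 15971685 to 26346787 per library, cover the listed genes and may fall short of the whole libraries. A value of 1 read corresponded to 0.747 to 1.50 normalized reads and a count of 0 allowed up to 3 reads, or 2.24 to 4.49 normalized reads, depending on the library. These floors cover counting error only, since reads without molecular identifiers are not independent molecules. Gene names are those of the table. Among its gene identifiers, 11952 were found in a table of current names and 99 were not, and 4 names that a spreadsheet had turned into dates were restored from their identifiers.

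The plan, fixed before the data were examined, assumed a table of counts and edgeR's quasi-likelihood test, with limma for normalized values. Because the deposited unit is normalized, the main test was limma (version 3.58.1 in R 4.3.3) with an empirical Bayes trend on log2(normalized reads + 1), on genes with a mean of at least 10 over the 7 libraries. That kept 11174 genes and left out 877. The test was two-sided, with a Benjamini-Hochberg adjustment and a threshold of 0.05, and no covariate. edgeR (version 4.0.16) and DESeq2 (version 1.42.0) were run on the recovered whole reads as alternatives chosen after seeing the data. DESeq2's Cook's distance filter gave no p for 2214 genes. Correlations and permutation tests were run in R. Recovery of reads and summaries used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures used matplotlib 3.10.9.

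Gene lists were fixed before the data were examined, 26 in all: ribosome components, translation factors, stages of spermatogenesis, Y-linked genes, testis proteasome subunits, energy metabolism, chaperones, classes of non-coding RNA, and markers of hub and cyst cells, accessory gland, muscle, fat body, neurons and immune response. Lists with at least 5 tested members, 24 of them, were tested with limma's camera at a preset inter-gene correlation of 0.01, with an adjustment over those 24. An estimated correlation and the rotation test fry were the checks. The share of reads from each list was compared by an exact permutation test, two-sided, whose smallest possible p with 3 against 4 libraries is 0.0286.

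The genes named in the text follow a rule fixed in advance. RpL22 and RpL22-like are always named. Among genes past the limma threshold, up to 12 per direction with the largest changes are named. From each list come up to 3 members past the threshold or, where none passes, the 2 members with the highest mean. As no gene passed, the first and last parts of the rule gave 52 genes, of which the text gives examples from each group. The 21 genes called in the authors' table, aub, mt:srRNA, abundant genes with changes of at least 2-fold and CG9920 were added after their values were seen.

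The tests were tried on simulated libraries with the real means and library sizes, and with the typical spread of the real libraries at each level. Genes were drawn independently. Spread particular to a gene, correlation between genes and differences between whole libraries were therefore absent, and the rates hold for that setting only. With changes of 2-, 4- and 16-fold in about 200 genes each, limma recovered 4.98%, 18.9% and 34.3% of the changed genes of all levels. Among 150 changed genes with means of at least 5000, it recovered 48.0%, 98.0% and 100%. In 10 simulations with no change, limma called 0 genes in each, edgeR 0 to 1 and DESeq2 74 to 103 with a median of 92.

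Alternatives were quantile normalization, scaling to library totals, TMM scaling, filters and pseudocounts, limma without the trend or with robust empirical Bayes, voom, the 2 count tests, stricter thresholds, a replicate block, and leaving out each library. DESeq2's size factors, planned as an alternative, are the deposited scaling itself. Results were also compared over the splits of the 7 libraries into 3 and 4, 35 with the real one, of which 24, again with the real one, were run for DESeq2.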

Results

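RNA was recovered from Drosophila melanogaster testis by precipitating ribosomes with antibodies specific to either eRpL22 or eRpL22-like. These paralogous large-subunit ribosomal proteins are both made in the male germline, and the study asks which RNAs are found on ribosomes that carry each of them. The labels list 4 replicate pulldowns for each paralogue from wild-type flies. They list no input RNA and no mock precipitate. RNA held by the ribosomes thus cannot be told apart from background shared by both pulldowns. The deposited table holds values for 7 of these 8 libraries, 3 from the eRpL22 pulldown and 4 from the eRpL22-like pulldown, and eRpL22 replicate 4 was not analysed here. Over the 12051 genes listed, the reads recovered from the table numbered 15971685, 19762521 and 26346787 in eRpL22 replicates 1, 2 and 3. They numbered 25159184, 24378034, 22448043 and 24635199 in eRpL22-like replicates 1 to 4. Nothing in the labels says whether replicates came from separate batches of flies, so the p-values measure the spread between these libraries, which may be technical. Log2 fold changes are given as eRpL22-like over eRpL22. Those of limma are on the log2(normalized reads + 1) scale, which understates changes of low genes, whereas those of the authors come from DESeq2. Ratios are of mean normalized reads.

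Transcripts of sperm development were among the most abundant protein-coding RNAs of both pulldowns, and no transcript passed the test between the pulldowns. S-Lap1, a leucyl aminopeptidase of sperm (FBgn0035915), stood at 167327 ± 14002 normalized reads (SD, n = 3) with eRpL22 and 145503 ± 13921 (SD, n = 4) with eRpL22-like. Mst87F, a sperm tail protein (FBgn0002862), stood at 138867 ± 23402 (SD, n = 3) and 111023 ± 17750 (SD, n = 4). Their log2 fold changes of -0.20 and -0.32 had unadjusted limma p-values of 0.0362 and 0.00832, and their library values overlapped between pulldowns. The direction for S-Lap1 depended on scaling, at -0.10 with library totals only and 0.08 with quantile normalization. Of the 11174 genes tested by limma with Benjamini-Hochberg adjustment, 0 passed 0.05, and the smallest adjusted p was 0.945. The unadjusted p was under 0.05 for 459 genes, or 4.11%. edgeR on the recovered whole reads also called 0 of 9516 genes, with 377 at an unadjusted p under 0.05, whereas DESeq2 on the same reads called 172 of 8688 genes, 121 higher and 51 lower with eRpL22-like. The authors' deposited table, also from DESeq2, called 21 genes, with an adjustment over all 12051 genes. DESeq2 on the recovered reads over all 12051 genes, without its Cook's and independent filters, called 725. That fit had 1750 genes at an unadjusted p under 0.05, against 666 in the authors' table. The authors' p-values were thus not reproduced, although most of their fold changes were.

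Transcripts of the paralogue genes themselves had lower means in the eRpL22-like pulldown, with overlapping library values and no call. RpL22 (FBgn0015288) was at 8177 ± 7160 normalized reads (SD, n = 3) with eRpL22 and 3803 ± 2141 (SD, n = 4) with eRpL22-like. RpL22-like (FBgn0034837) was at 1487 ± 498 (SD, n = 3) and 647 ± 264 (SD, n = 4). The log2 fold change was -1.01 with an SE of 0.51 for RpL22 and -1.24 with an SE of 0.84 for RpL22-like, with unadjusted limma p-values of 0.0562 and 0.146. The RpL22 mean rested on 16441 normalized reads in eRpL22 replicate 1, against 3861 and 4228 in the other eRpL22 libraries. Without that library its log2 fold change was -0.34, and without eRpL22-like replicate 4 it was -0.49.

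The 21 genes called in the authors' deposited table were mostly near absence in the libraries of one pulldown and well represented in most libraries of the other. These genes are named here because of those calls, after their values were seen. Src42A (FBgn0264959), a Src-family tyrosine kinase, ranged from 109 to 157 normalized reads in the 3 eRpL22 libraries and from 1497 to 2570 in the 4 eRpL22-like libraries, a ratio of means of 15.7. CG5346 (FBgn0038981) went from 52.0 ± 13.5 (SD, n = 3) with eRpL22 to 909 ± 396 (SD, n = 4) with eRpL22-like, and CG6686 (FBgn0032388) from 63.2 ± 49.6 (SD, n = 3) to 1345 ± 967 (SD, n = 4). Tim17b1 (FBgn0037310), a subunit of the mitochondrial inner-membrane protein translocase, had the highest levels among the 13 genes higher with eRpL22-like, at 1609 ± 254 normalized reads (SD, n = 3) and 6057 ± 2603 (SD, n = 4), a ratio of 3.76. The other 9 of these 13 genes had at most 87.7 normalized reads in any eRpL22 library. They were CG10628, drm, a zinc-finger protein, the potassium channel gene Shal, CG7970, CG31522, CG42671, CG3309, the non-coding CR44411 and cv-2, which encodes a secreted BMP-binding protein. Of the 8 genes lower with eRpL22-like, coro (FBgn0265935), which encodes the actin-binding protein coronin, was at 3695 ± 1326 (SD, n = 3) and 851 ± 338 (SD, n = 4), a 4.34-fold lower mean. CG4297, CG11399, CG5854, CG17985, the endoribonuclease gene EndoU, CG13694 and CG33052 had at most 94.1 normalized reads in any eRpL22-like library. The pulldown with the higher mean also held low libraries. CG17985, EndoU and CG33052 fell to 1.02, 2.04 and 15.1 in an eRpL22 library, and cv-2 fell to 26.1 in an eRpL22-like library.

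In the authors' deposited table, Src42A had a log2 fold change of 3.97 with a DESeq2 adjusted p of 6.87e-14, Tim17b1 1.91 with 0.00525 and coro -2.12 with 0.0151. Limma gave log2 fold changes of 3.95 with an SE of 0.95 for Src42A, 1.84 with an SE of 0.47 for Tim17b1 and -2.12 with an SE of 0.65 for coro, at unadjusted p-values of 0.000204, 0.000395 and 0.00263 and adjusted p-values of 0.945. The authors' calls came from these same libraries, so agreement with them here is not separate support. All 21 genes had the same direction and an unadjusted p under 0.05 in limma, and 20 were among the 172 calls of DESeq2 on the recovered reads. Of the 21, 19 had library values that did not overlap between pulldowns. For EndoU the gap, from 1.82 to 2.04 normalized reads, lay under the floor of counting. The 2 with overlapping values were CG17985, at 1974, 1.02 and 1476 normalized reads in the eRpL22 libraries, and CG42671, which reached 56.1 in an eRpL22 library and had 52.0 in the lowest eRpL22-like library. Over all 11174 genes, 574 (5.14%) had library values that did not overlap, 266 higher and 308 lower with eRpL22-like, where chance gives 5.71% for 3 libraries against 4.

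**Figure D1:**
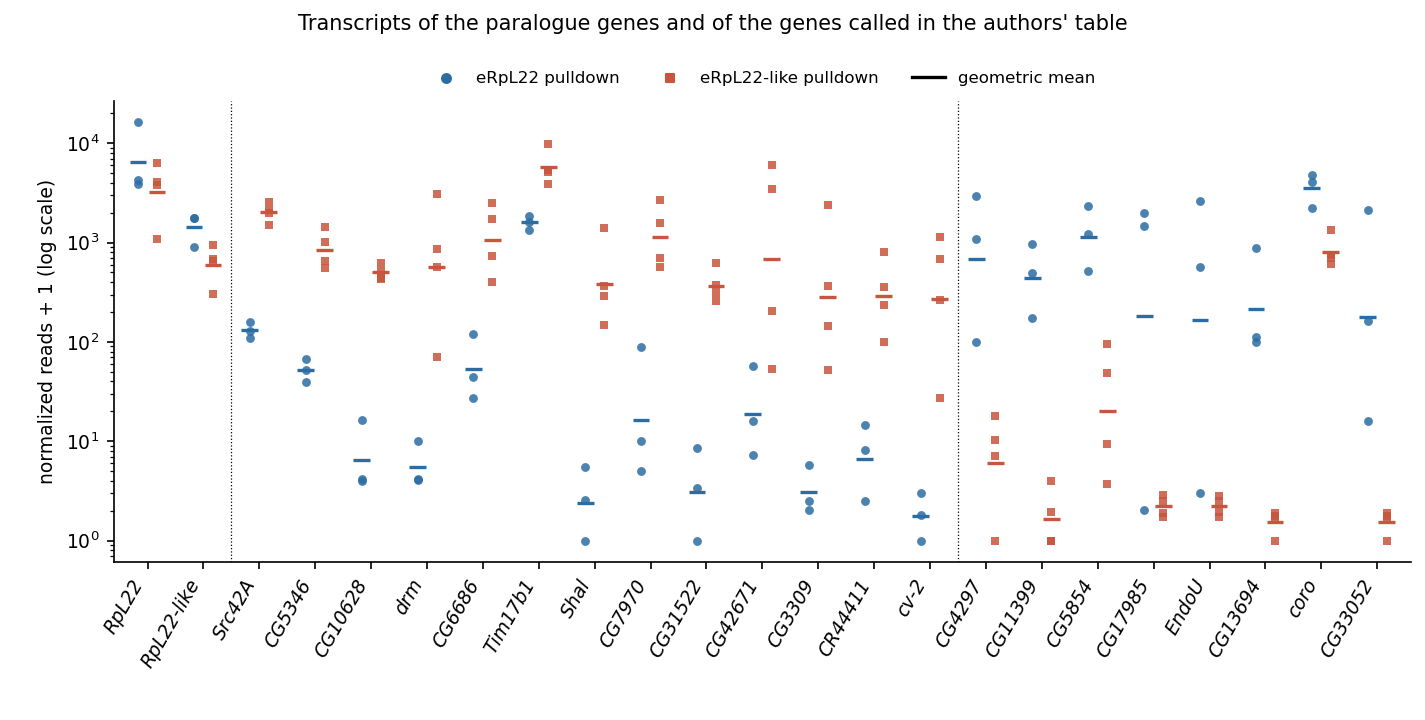
Normalized reads + 1 (log axis) of RpL22, RpL22-like and the 21 genes called in the authors' deposited table, with each of 3 eRpL22 (circles) and 4 eRpL22-like (squares) libraries as a point and the geometric mean as a line; dotted lines part the paralogue genes, the 13 genes higher and the 8 genes lower with eRpL22-like. Points of RpL22 and RpL22-like overlap between pulldowns, whereas Src42A lies at 109 to 157 normalized reads in the eRpL22 libraries and at 1497 to 2570 in the eRpL22-like libraries.

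Most abundant transcripts had an estimated change under 2-fold between the pulldowns. The 770 genes with a mean of at least 5000 normalized reads held 58.6% to 62.5% of the reads of each library. Of them, 762 (99.0%) had an estimated change under 2-fold. Limma called 0 of the 770 and gave 52 an unadjusted p under 0.05, a larger share than the 459 of all 11174 genes. For 510 of the 770 (66.2%) the 95% interval of the fold change lay within 2-fold either way. The 8 exceptions were named after their values were seen. Vha13, a subunit of the vacuolar ATPase, had 4446 ± 516 normalized reads (SD, n = 3) with eRpL22 and 9001 ± 1754 (SD, n = 4) with eRpL22-like, and CG3662 had 3022 ± 749 (SD, n = 3) and 7061 ± 2265 (SD, n = 4). Of the 8, DESeq2 on the recovered reads called Vha13 (adjusted p = 0.0204) and CG3662 (adjusted p = 0.0452) alone. CG31546, prtp and CG6409 also had higher means with eRpL22-like, and CG8042, CG15111 and RpL22 lower means, with a largest absolute log2 fold change of 1.24, for prtp. The library values of Vha13, CG3662, CG31546 and CG8042 did not overlap between pulldowns. The median half-width of the 95% interval grew from 1.597-fold in this class to 2.57-fold for the 2713 genes with means of 1000 to under 5000, 19.6-fold for the 5090 genes at 100 to under 1000, and 38.6-fold for the 2601 genes at 10 to under 100. Changes of several fold were therefore not detectable for most genes under 1000 normalized reads.

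**Figure D2:**
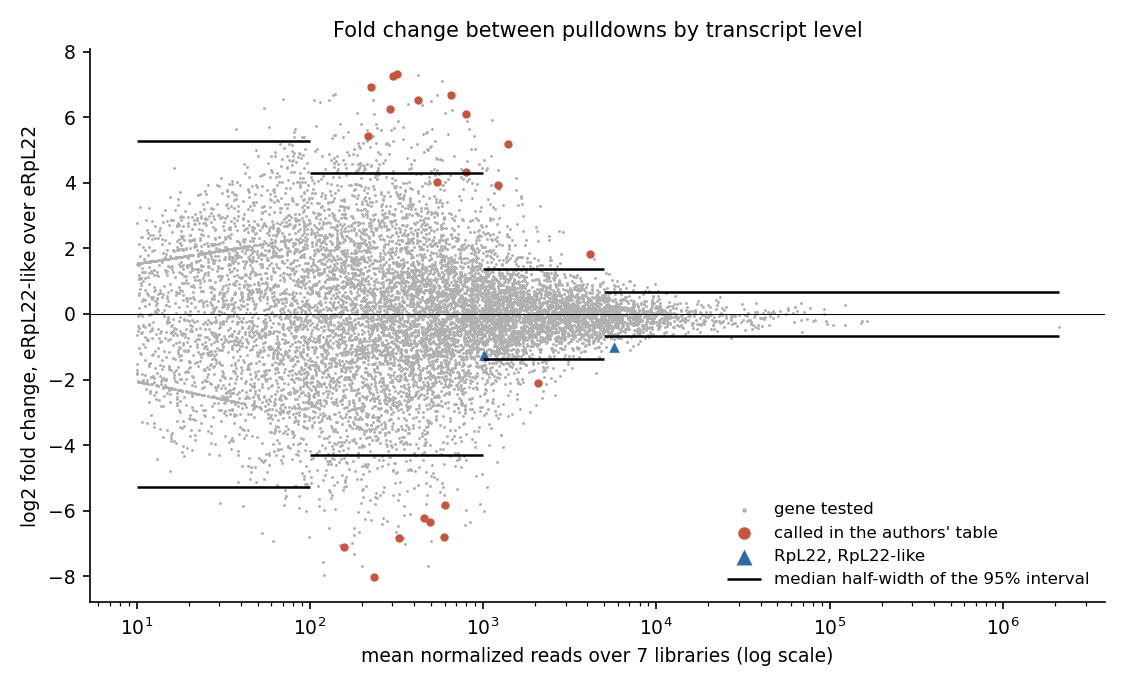
Log2 fold change (eRpL22-like over eRpL22, log2 of normalized reads + 1) against the mean normalized reads over 7 libraries (log axis) for the 11174 genes tested, with the 21 genes called in the authors' deposited table as larger circles, RpL22 and RpL22-like as triangles, and black lines at plus and minus the median half-width of the 95% interval in each of 4 level classes. The spread of fold changes narrows with level, and the half-width falls from 38.6-fold at means of 10 to under 100 to 1.597-fold at means of at least 5000.

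Ribosomal RNA genes as a list were lower in the eRpL22-like pulldown. All 11 members tested had a negative log2 fold change, with a mean of -0.88 and a median of -0.65, and the list passed camera at a preset inter-gene correlation (p = 0.00103, adjusted p = 0.0247 over 24 lists tested). The call did not hold with an estimated correlation (adjusted p = 0.960), and fry gave p = 0.0701. No member was called over all genes or adjusted over the list alone, and 5 had an unadjusted limma p under 0.05. The mitochondrial mt:lrRNA stood at 2491880 ± 1261460 normalized reads (SD, n = 3) with eRpL22 and 1804430 ± 556008 (SD, n = 4) with eRpL22-like, and took 11.2% ± 4.61 (SD, n = 3) and 8.86% ± 2.09 (SD, n = 4) of the reads. Its lower mean rested on 3943640 normalized reads in eRpL22 replicate 1, against 1868780 and 1663220 in the other eRpL22 libraries, and its log2 fold change of -0.40 was -0.01 without that library. 28SrRNA-Psi:CR45859, a 28S pseudogene, stood at 82573 ± 27612 (SD, n = 3) and 58634 ± 25372 (SD, n = 4). mt:srRNA, named after its values were seen, stood at 13391, 3968 and 4623 in eRpL22 replicates 1, 2 and 3 and at 2658 ± 834 (SD, n = 4) with eRpL22-like, without overlap. Most of the share of reads from the list was mt:lrRNA, so a test of that share is mainly a test of this mitochondrial RNA. The difference in the share was within the spread by an exact permutation test (11.9% ± 4.68 and 9.28% ± 2.10, two-sided p = 0.429, adjusted p = 0.971 over 26 lists). It rested on the 17.2% of eRpL22 replicate 1, against 10.02% and 8.37% in eRpL22 replicates 2 and 3. The pseudogenes are near-identical copies that can share reads, so their values are uncertain. The call was lost when eRpL22 replicate 1, eRpL22 replicate 2, eRpL22-like replicate 2 or eRpL22-like replicate 4 was left out, at camera adjusted p-values of 0.340, 0.0879, 0.441 and 0.504.

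Cytosolic ribosomal protein genes did not pass as a list. Of 88 members, 70 had negative log2 fold changes with a median of -0.26 (camera p = 0.0138, adjusted p = 0.165, adjusted p = 0.960 with an estimated correlation), and 0 were called over all genes or adjusted over the list alone. RpL8 was at 15557 ± 6803 normalized reads (SD, n = 3) with eRpL22 and 13840 ± 3828 (SD, n = 4) with eRpL22-like, and RpL41 at 15034 ± 5780 (SD, n = 3) and 11897 ± 4180 (SD, n = 4). The list's mean log2 fold change of -0.26 became 0.04 without eRpL22 replicate 1, and the list passed camera without eRpL22 replicate 2, eRpL22 replicate 3, eRpL22-like replicate 1 or eRpL22-like replicate 3 at adjusted p-values of 0.0338, 0.00431, 0.000852 and 0.0216. Among 9 genes listed in advance as testis-biased ribosomal protein paralogues, 6 were negative with a median of -0.38 (camera adjusted p = 0.882). Whether each member is testis-biased or such a paralogue was not tested here. RpS19b was at 2866 ± 1276 (SD, n = 3) and 4504 ± 2156 (SD, n = 4) and RpL24-like at 4115 ± 2764 (SD, n = 3) and 3978 ± 908 (SD, n = 4). Mitochondrial ribosomal proteins leaned the other way, with 42 of 71 positive and a median of 0.38, and also did not pass (camera adjusted p = 0.554). Their share of reads was 0.242% ± 0.0228 (SD, n = 3) with eRpL22 and 0.309% ± 0.0262 (SD, n = 4) with eRpL22-like. The library values of this share did not overlap between pulldowns, which chance gives in 5.71% of cases for 3 libraries against 4. The exact permutation two-sided p was 0.0571. The adjusted p was 0.971, which 1 list alone could not have brought under 0.05. mRpS17 was at 1990 ± 755 (SD, n = 3) and 3341 ± 1572 (SD, n = 4). The 47 translation factors divided into 23 positive and 24 negative (camera adjusted p = 0.882), with pAbp, the cytoplasmic poly(A)-binding protein gene, at 43115 ± 11522 (SD, n = 3) and 32778 ± 7542 (SD, n = 4) and the elongation factor gene eEF1alpha1 at 36982 ± 23226 (SD, n = 3) and 37079 ± 20800 (SD, n = 4).

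Genes of the successive stages of spermatogenesis did not pass in any list. For 33 sperm chromatin and sperm tail genes the median log2 fold change was -0.06 (camera adjusted p = 0.882), and the list took 6.28% ± 0.617 (SD, n = 3) of the reads with eRpL22 and 6.21% ± 0.467 (SD, n = 4) with eRpL22-like. Medians were -0.10 for 17 post-meiotic cup and comet genes (camera adjusted p = 0.882), 0.18 for 15 meiotic entry and division genes (camera adjusted p = 0.882), -0.06 for 15 regulators of the spermatocyte transcription program (camera adjusted p = 0.882) and -0.12 for 13 germline stem cell and spermatogonial genes (camera adjusted p = 0.882). w-cup was at 31648 ± 7595 normalized reads (SD, n = 3) with eRpL22 and 25828 ± 4439 (SD, n = 4) with eRpL22-like, and orb2, a CPEB-family RNA-binding protein gene, at 13301 ± 2759 (SD, n = 3) and 12407 ± 2442 (SD, n = 4). The meiotic translational regulators fest and bol were at 43618 ± 4668 (SD, n = 3) and 34852 ± 7224 (SD, n = 4), and at 16753 ± 3316 (SD, n = 3) and 20076 ± 8229 (SD, n = 4). Of the spermatocyte list, vis was at 1111 ± 381 (SD, n = 3) and 1313 ± 379 (SD, n = 4). tud, a piRNA pathway gene, was at 3503 ± 1976 (SD, n = 3) and 2974 ± 1291 (SD, n = 4). Adjusted over the list alone, 1 stem cell and spermatogonial gene passed, aub, named after its value was seen. aub, which encodes a PIWI protein, had 362, 3.06 and 2.38 normalized reads in the eRpL22 libraries and 1040, 269, 1456 and 2517 in the eRpL22-like libraries (limma adjusted p = 0.0344 over the list alone and 0.945 over all genes), with overlapping values. No gene of the other 25 lists passed adjusted over the list alone.

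Y-linked genes (12 tested, median 0.24, camera adjusted p = 0.882) and testis-specific proteasome subunits (14 tested, median -0.16, camera adjusted p = 0.882) also did not pass. ARY was at 1338 ± 440 normalized reads (SD, n = 3) with eRpL22 and 1373 ± 374 (SD, n = 4) with eRpL22-like, and Prosalpha6T at 8753 ± 2551 (SD, n = 3) and 7564 ± 1026 (SD, n = 4). Heat shock and chaperone genes had a median of -0.09 over 18 genes (camera adjusted p = 0.882), and the mitochondrial chaperonin gene Hsp60C was at 55938 ± 9901 (SD, n = 3) and 56008 ± 5431 (SD, n = 4). For 62 nuclear-encoded oxidative phosphorylation genes the median was 0.03 (camera adjusted p = 0.938), and for 19 mitochondrially encoded transcripts it was 0.06 (camera adjusted p = 0.882). COX5A was at 18323 ± 5493 (SD, n = 3) and 14481 ± 3520 (SD, n = 4), and mt:CoI at 20067 ± 5386 (SD, n = 3) and 20585 ± 2716 (SD, n = 4).

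Markers of cells other than the germline were detected in both pulldowns, at shares of reads that differed by less than the spread between replicates. Accessory gland and ejaculatory tract genes took 0.513% ± 0.114 (SD, n = 3) of the reads with eRpL22 and 0.505% ± 0.0957 (SD, n = 4) with eRpL22-like, an exact permutation two-sided p of 0.943 (adjusted p = 0.971), and the list of 24 genes did not pass (camera adjusted p = 0.882). Acp36DE, a seminal fluid protein gene, was at 17722 ± 7010 normalized reads (SD, n = 3) and 16440 ± 6822 (SD, n = 4). Fat body and hemolymph markers (10 tested, camera adjusted p = 0.882), muscle markers (21 tested, camera adjusted p = 0.882), neuronal markers (11 tested, camera adjusted p = 0.554), antimicrobial peptides (7 tested, camera adjusted p = 0.882) and somatic hub and cyst cell markers (19 tested, camera adjusted p = 0.882) did not pass either. Obp99a was at 34071 ± 7644 (SD, n = 3) and 29827 ± 6192 (SD, n = 4), Msp300 at 11825 ± 4229 (SD, n = 3) and 7848 ± 2506 (SD, n = 4), and Fas3, a hub cell adhesion gene, at 1565 ± 979 (SD, n = 3) and 1693 ± 472 (SD, n = 4).

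Non-coding RNA lists gave no further call. The 1064 long non-coding and antisense RNA genes had a median of -0.11 (camera adjusted p = 0.882), with CR32658 at 31332 ± 5207 normalized reads (SD, n = 3) with eRpL22 and 25545 ± 1319 (SD, n = 4) with eRpL22-like. Small nucleolar and scaRNAs (8 tested, camera adjusted p = 0.938) and spliceosomal snRNAs (7 tested, camera adjusted p = 0.882) did not pass. Replication-dependent histone genes, with 2 members over the minimum level, and tRNA genes, with 1, had too few members for camera, and no member was called. Antisense genes and their partners cannot be told apart without a stated use of strand. The median, the mean and the camera direction differed in sign for 8 of the 24 lists tested, among them the accessory gland list (median -0.17, mean 0.28) and the mitochondrially encoded list (median 0.06, mean -0.43).

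**Figure D3:**
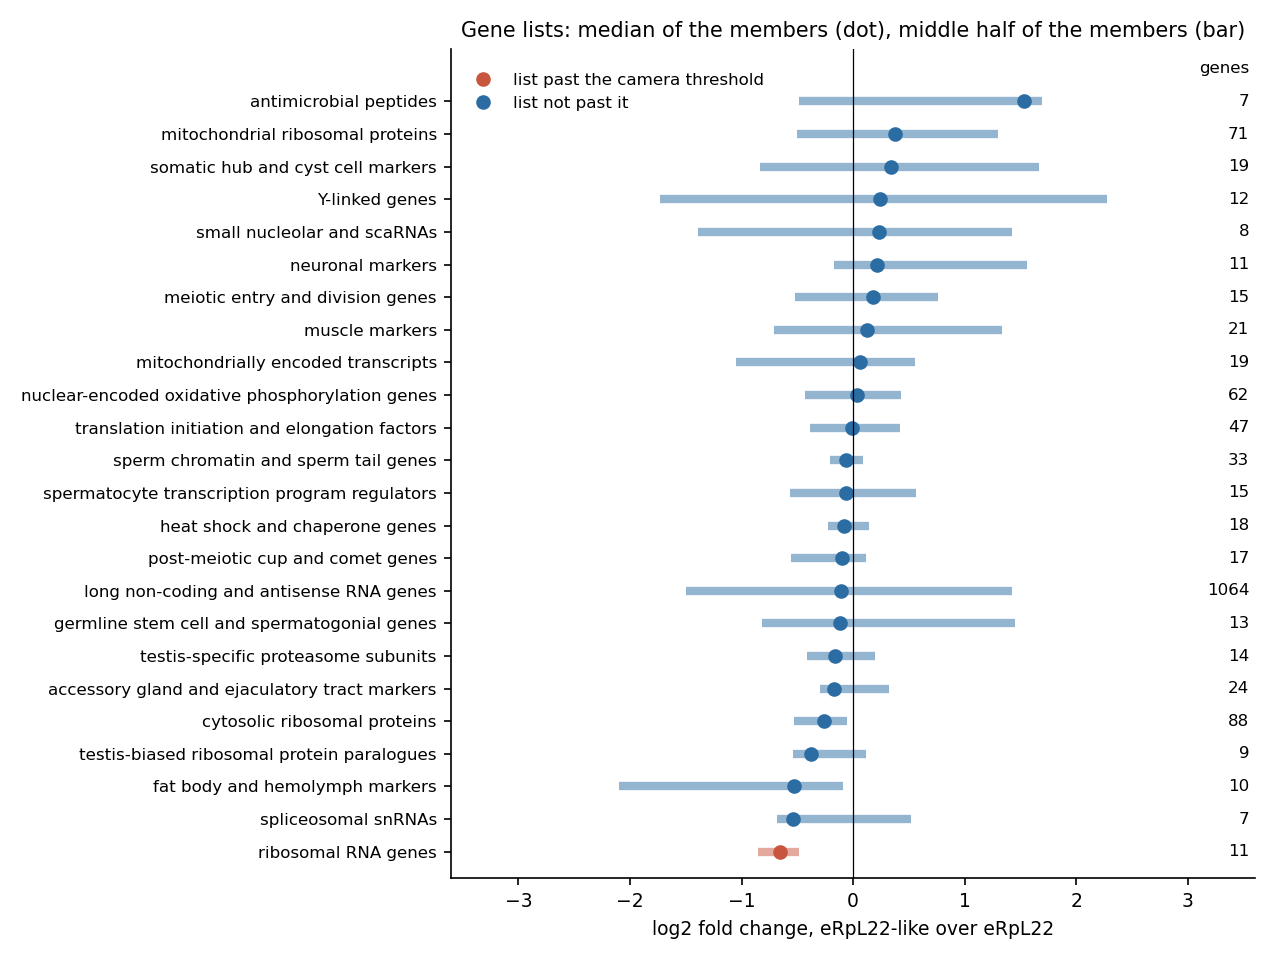
Log2 fold change (eRpL22-like over eRpL22, log2 of normalized reads + 1) of the members of the 24 lists tested, with the median as a dot, the middle 50% of members as a bar and the number of genes tested at the right. The ribosomal RNA genes, in red, are the list past the camera threshold, with a median of -0.65.

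Libraries of the same pulldown correlated no better than libraries of different pulldowns, beyond the spread between pairs. The mean Spearman correlation across 11174 genes, which are not independent replicates, was 0.733 within pulldowns and 0.731 between them, a difference of 0.00196 against an SD of 0.0250 over the pairs within a pulldown. Single pairs ranged from 0.693, for eRpL22 replicate 1 with eRpL22-like replicate 1, to 0.787, for eRpL22-like replicates 2 and 4. On the first principal component, with 21.6% of the variance, eRpL22-like replicates 1 and 3 scored 164 and 193 and the other 5 libraries -98.9 to -37.7. On the second, with 20.1%, eRpL22-like replicates 1 and 3 lay on opposite sides, at -219 and 193, and the others scored -5.93 to 14.8. The same libraries, eRpL22-like replicates 1 and 3, had 2923 and 3014 genes at 0 reads, against 1411 and 1670 in eRpL22-like replicates 2 and 4 and 2098 to 2245 in the eRpL22 libraries.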

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

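The comparison of each library with the rest of its group was made for the 4 eRpL22-like libraries alone. The 3 eRpL22 libraries were not screened, so a library apart among them would not be listed here. Of 102 reported values, 10 had 1 eRpL22-like library far from the other 3, where chance gives about 5.1 for separate values with a normal spread. In all 10 the library apart was the highest, as skewed values would give, and some of the values overlap. The count is above that expectation, but the expectation does not hold for such values. Neither an excess over chance nor its absence is shown.

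eRpL22-like replicate 3 stood apart for 6 of the 10. The spliceosomal snRNA genes took 0.01005% of its reads, against 0.00247% to 0.00313% in the other eRpL22-like libraries. Their most abundant members stood apart with them: snRNA:U1:95Cc at 984 normalized reads, against 154 to 259, and snRNA:U1:82Eb at 623, against 184 to 251. In the other pulldown, eRpL22 replicate 1 was about as high, with a share of 0.00934%, snRNA:U1:95Cc at 946 and snRNA:U1:82Eb at 758. The share was 0.00328% and 0.00319% in eRpL22 replicates 2 and 3. These U1 genes are near-identical copies that can share reads, so they are not separate evidence. snoRNA:Or-CD8 stood at 289 in eRpL22-like replicate 3 and at 0 to 0.747 in the other eRpL22-like libraries. It was at 263, 0 and 109 in eRpL22 replicates 1, 2 and 3. chinmo, a gene of somatic cyst stem cells, stood at 7225, against 1373 to 2056, and fest at 45646, against 30675 to 32131.

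In eRpL22-like replicate 1, CG3309, a gene called in the authors' deposited table, stood at 2378 normalized reads, against 51.3 to 366, and the Y-linked ARY at 1928, against 1146 to 1263. The neuronal gene nSyb stood at 2474 in eRpL22-like replicate 4, against 125 to 422. tRNA:Arg-ACG-1-10 stood at 35.8 in eRpL22-like replicate 2 and at 0 in the other eRpL22-like libraries.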

How the results depend on the processing

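The alternatives on recovered reads, robust limma, TMM scaling, some list settings and all settings for the library correlations were chosen after seeing the data. The count of 0 genes called held in 20 of 23 alternatives, and was 0 without any single library. The stricter thresholds among these 20 used the same fit, so they could only give 0. The rest of the 20 had 314 to 535 genes at an unadjusted p under 0.05. Their smallest adjusted p came nearest to the threshold in limma without the trend, at 0.0556. Quantile normalization called 1 gene, CG9920 (log2 fold change 0.53, limma adjusted p = 0.00395, against 0.27 and 0.945 in the reported fit). DESeq2 called 172 genes and, without its Cook's and independent filters, 725; the cause was tested only as described among the other observations. No scaling moved the median log2 fold change of all genes by over 0.1 (-0.0997 to 0.0669 over all alternatives). The 1 list past the camera threshold became 0 with quantile normalization, the replicate block, an estimated correlation and fry, and 0 to 2 with a library left out. The 4 fits with 2 lists all had the cytosolic ribosomal proteins as one of them. The other was the ribosomal RNA genes, except without eRpL22 replicate 2, where it was the mitochondrially encoded transcripts (adjusted p = 0.0338). These calls used the preset correlation. In the reported fit the mitochondrially encoded list had an estimated correlation of 0.489, and camera with it gave an adjusted p of 0.960. The mean log2 fold change of ribosomal RNA genes stayed negative in all 17 alternatives. It was no longer past the threshold with quantile normalization (-0.77, adjusted p = 0.0736), the replicate block (-0.77, adjusted p = 0.861), which also takes eRpL22-like replicate 4, without a partner, out of the comparison (without that library alone, -0.77 and 0.504), an estimated correlation (-0.88, adjusted p = 0.960) and fry (-0.88, adjusted p = 0.918). The last 2 settings change the test, not the value. With a library left out it ranged from -1.16 to -0.69, at adjusted p-values of 0.000798 to 0.504; the cause was not tested. Replicate numbers did not pair the libraries: same-numbered libraries correlated at 0.00710, 0.0195 and 0.00995 in their deviations from the group means, and eRpL22 replicate 3 alone correlated best with its own number. The replicate block left 0 genes called, with 314 at an unadjusted p under 0.05. The 52 genes named by rule gave 1084 values over 21 alternatives, 1055 of them within 1 SE of the reported value, 0 past the threshold and 59 of the other sign, in 25 genes. The authors' 21 genes gave 437 values, 0 of the other sign and 41 past the threshold, all with DESeq2. They were called from these same libraries, so their steady sign is not separate support. The difference in correlation within and between pulldowns stayed between -0.00124 and 0.00704. No alternative varied the depth, at which 1 read corresponded to 0.747 to 1.495 normalized reads, so changes of genes near that level are not resolved. No alternative could leave out eRpL22 replicate 4.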

Other observations

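The most abundant RNA in both pulldowns was mt:lrRNA, and CG18628, S-Lap1, CG4836, Mst87F, CG9920, dj and ocn were among the most abundant protein-coding transcripts. dj, which encodes a sperm tail protein, was at 109127 ± 6551 normalized reads (SD, n = 3) with eRpL22 and 87943 ± 10494 (SD, n = 4) with eRpL22-like, without overlap (limma unadjusted p = 0.00781, adjusted p = 0.945). ocn was at 88007 ± 13107 (SD, n = 3) and 97178 ± 3243 (SD, n = 4), and CG9920 at 109023 ± 11614 (SD, n = 3) and 131735 ± 12750 (SD, n = 4). The cell cycle inhibitor gene rux was at 867 ± 361 (SD, n = 3) and 2776 ± 870 (SD, n = 4), and eRF1, the translation termination factor gene, at 6427 ± 1368 (SD, n = 3) and 3195 ± 902 (SD, n = 4), both without overlap and at limma adjusted p-values of 0.945. These genes were chosen after their values were seen.

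Tests of the on-off scatter, of correlated list members, and the split counts for limma calls and non-overlapping genes were chosen after the results were seen. The first pattern is that many transcripts switched between near 0 and well over 100 normalized reads among libraries of the same pulldown, as aub, CG17985 and EndoU did. Sequencing depth alone does not account for it: among 8573 genes with means of at least 100, 3021 of 60011 library values were at 0 reads, 41.9 times the 72.1 that Poisson sampling gives. A candidate explanation is that few RNA molecules were captured and each was amplified into many reads, since the within-group variance then grows with the mean to a power near 1. That power was 1.09 (95% bootstrap interval 1.06 to 1.11, 6059 genes). The paralogue is the same within a pulldown and so cannot produce this scatter, and no other biological explanation was tested.

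The second pattern is that DESeq2 called 172 genes where limma and edgeR called 0. Chance cannot be excluded, since 16 of the 24 splits run gave as many DESeq2 calls, with 426 the highest of the others. The split with 426 calls set eRpL22 replicate 1 and eRpL22-like replicates 1 and 3 apart from the others, so libraries differ along lines that do not follow the pulldown. Simulated libraries with no change, independent genes and the typical spread of the real ones at each level gave a median of 92 DESeq2 calls, against 172. Spread alone could thus account for part of the calls. The simulation held no capture or amplification step, so it cannot tell few captured molecules from other sources of spread. A difference between the paralogues' ribosomes remains open for genes such as Src42A, at 109 to 157 and 1497 to 2570 normalized reads in the libraries of the pulldowns, although limma did not call it (adjusted p = 0.945).

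The third pattern is the lower ribosomal RNA genes with eRpL22-like. A single library does not account for the mean log2 fold change of the members, since its value nearest to 0 with a library left out was -0.69, although the call was lost without any of 4 libraries. Members that move together within a group may have produced the call, as near-identical copies sharing reads would: their estimated correlation was 0.413, and camera with it gave p = 0.189. Chance cannot be excluded, since 4 of 35 splits gave a camera p as small as the real 0.00103, with 5.46e-06 the smallest of the others. The paralogue itself stays open and was not tested apart from this comparison.

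The splits could not test the limma calls, since every split, 35 of 35, gives at least the real 0, with 5 the highest of the others. Other counts of the comparison did not stand out among the splits, so chance cannot be excluded for them. As many genes at an unadjusted p under 0.05 as the real 459 came from 20 of 35, with 748 the highest. As many non-overlapping genes as the real 574 came from 15 of 35, with 829 the highest. As many gene lists past the threshold as the real 1 came from 22 of 35, with 6 the highest.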
